A study of Homo sapiens with 2 samples.

How the data were processed

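HT-29 colorectal adenocarcinoma cells were transfected with an siRNA against firefly luciferase or against IFITM1, and total RNA was taken 72 h later, per the labels. Per the labels' protocols, RNA was column purified and amplified to biotin-labelled cRNA. Each of the 2 samples was read on 1 single-colour Affymetrix array, and no replicate array was analysed here. Probe signals were summarised per probe set with MAS5 per the submitters' processing notes, and its version is not given in the sources used here. The deposited values are intensities, that is MAS5 signals on a linear scale, all above 0. On both arrays the mean signal after removing 2% of probe sets at each end was 500.1, so the arrays had been scaled to a common level. Detection calls were not used here. The number of arrays limits the precision of every value.

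The probe table named 1 gene for 41091 of the 54613 probe sets that are not controls, several for 1801 and none for 11721. Symbols were updated through the Entrez identifier in a RefSeq gene table of the human assembly GRCh38.p14, in which 41037 probe sets (99.9%) found a match. Only probe sets that name 1 gene were used for gene values. No coordinates were used except to find which genes neighbour each other in that table.

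Signals were taken to log2 as deposited, with no further scaling or centring, and the log2 ratio is siIFITM1 over siLuc. Where a gene had several probe sets, the one with the highest mean log2 signal over both arrays represented it. A gene passed the filter if that mean was at or above the median over all probe sets that are not controls, a signal of 57.4, which left 12225 of 19775 genes. Genes at or above the 75th percentile, a signal of 393, are called brighter and the other genes that passed are called dimmer. The comparison was described by size, because 1 array per siRNA allows no test. The yardsticks were the SD of log2 ratios between probe sets of the same gene and the ratios of the hybridisation and poly-A control probe sets. Shares of genes have exact (Clopper-Pearson) 95% intervals, which cover counting error only and treat genes as independent.

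For each of 25 gene lists, the median log2 ratio of the members that passed was placed among the medians of 10000 random lists of the same size, drawn within 20 bins of mean signal. The lists and all choices above were fixed before the data were examined. So was the rule for named genes. It took IFITM1, IFITM2 and IFITM3. It took the 12 highest and 12 lowest log2 ratios among genes with an official symbol that passed the filter, where every other probe set past the filter had the same sign. From each list outside the random range or described in the text it took up to 4 members with the largest absolute ratio under the same sign rule. CACNG4 and MUC5AC did not meet the sign rule over all probe sets past the main filter and were named with their other probe sets because they ranked high or low under the stricter filter. RPS6KA2, GRAMD1A and RGS16 were named because they made up a count of 3. The other genes of the stricter filter came from the same rule applied to brighter genes. The decision to describe those in the text was made after their values were seen.

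Alternatives fixed beforehand were median centring of log2 ratios, quantile normalization, subtraction of a loess trend of ratio on signal (span 0.3), a pseudocount of 32, no filter, a filter at the 75th percentile, the mean over a gene's probe sets, omission of probe sets whose IDs end in _x_at or _s_at (probes shared with other transcripts), thresholds of 1.5-fold and 3-fold, and a demand that at least 2 probe sets all pass the 2-fold line. A ranking of log2 ratios against the running spread of genes of similar signal, and ratios with signals below the filter floor raised to it, were added after the data were seen.

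The calculation was tested on simulated arrays for the siIFITM1 against siLuc comparison, with 12225 genes past the filter and the observed spread of ratios at each signal level. Of 100 genes shifted by a log2 ratio of 2 in either direction, 98% were recovered as 2-fold apart, and of 100 shifted by 1.5, 94%. Of 12025 genes with no such shift, 245 (2.04%) passed the 2-fold line. The spread used includes any real differences, so this is not a count expected without them. A list of 40 genes shifted by 0.3 had a median of 0.30 above all its random lists, and an unshifted list of 46 genes lay at percentile 44.4. In the simulation each probe set kept its observed mean signal, and noise was normal and independent between probe sets. The filter and joint variation of related genes were therefore not tested. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.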

Results

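Gene expression was measured in HT-29 cells, an established human colorectal adenocarcinoma line, 72 h after transfection with a small interfering RNA (siRNA). One sample received an siRNA against firefly luciferase (siLuc), a gene these cells lack, and served as the baseline. The other received an siRNA against IFITM1 (siIFITM1), an interferon-induced membrane protein that restricts the entry of enveloped viruses. There was 1 array per siRNA, so no difference below could be set against a spread between replicates, and no test or p-value is given. Each array held 54675 probe sets, and 12225 genes passed the filter on dim signals. The median signal was 63.9 on the siLuc array and 59.7 on the siIFITM1 array. All log2 ratios are siIFITM1 over siLuc.

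RNA quality was close on the 2 arrays. The log2 ratio of 3' to 5' signal for GAPDH was -0.13 in siLuc and -0.11 in siIFITM1, and for beta-actin it was 0.12 and 0.13. The 18 hybridisation control probe sets, which report RNA added in fixed amounts, had a median log2 ratio of -0.07 between the arrays (SD 0.057 over probe sets, range -0.13 to 0.05). The 24 poly-A control probe sets had a median of -0.11, with a wider range of -0.38 to 0.35.

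The comparison asked first how far IFITM1 mRNA was depleted. The signal of the probe set for IFITM1 (Entrez gene 8519) was 640 with siLuc and 237 with siIFITM1, which is 37.1% of the baseline and a log2 ratio of -1.43. Close relatives of IFITM1 were lower by similar amounts. IFITM2 went from 1177 to 481 (log2 ratio -1.29), and IFITM3 from 1525 to 490 (log2 ratio -1.64). A probe set annotated to both IFITM1 and IFITM2 went from 322 to 142 (log2 ratio -1.18). IFITM10, a more distant member of the family, had a log2 ratio of -0.42 at its brightest probe set, 0.23 at the next and -1.52 at the dimmest, which was below the filter (from 57.6 to 20.1). Every probe set that named IFITM1, IFITM2 or IFITM3 carried an ID ending that marks probes shared between transcripts, so how far the 3 genes were measured apart from one another is not known.

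**Figure D1:**
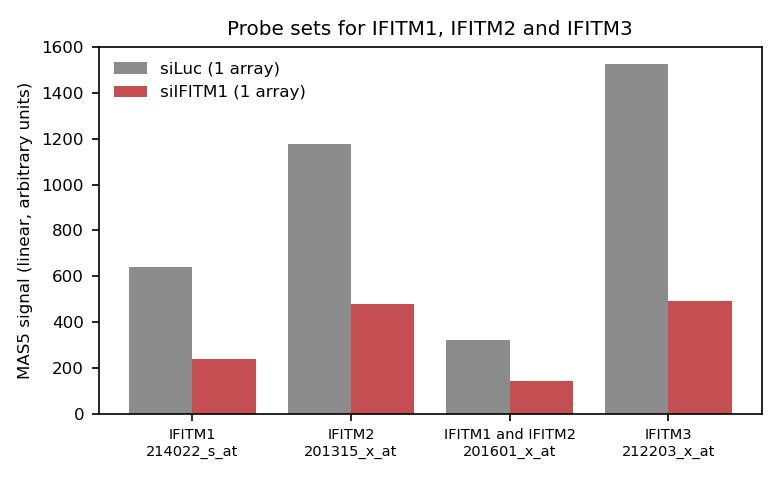
MAS5 signal (linear, arbitrary units) of the probe sets that name IFITM1, IFITM2 or IFITM3, with 1 bar per array and no error bars because each siRNA had 1 array. All 4 probe sets were lower with siIFITM1, by between 2.26-fold and 3.11-fold.

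Across the array, 124 genes were at least 2-fold higher with siIFITM1 and 246 were at least 2-fold lower, together 3.03% of the genes that passed the filter. The lower share was 66.5% (exact 95% binomial interval 61.4% to 71.3%, which covers counting error only). Most of these genes were dim. Among the 7793 brighter genes, whose mean signal exceeded the 75th percentile of all probe sets, 14 were 2-fold higher and 7 were 2-fold lower. Among the 4432 dimmer genes the counts were 110 and 239. The SD of log2 ratios between probe sets of the same gene was 0.193 among probe sets at or above the 75th percentile. It was 0.496 among the dimmer probe sets that passed the filter. The SD between different genes was 0.263 for brighter and 0.567 for dimmer genes. Without this split the SD was 0.367 between probe sets of the same gene and 0.404 between different genes. Of 59 genes past the line with several probe sets above the filter, 36 (61.0%) had all of these in one direction. The share among all 6087 genes with several such probe sets was 48.4%. Only 3 of the 59 were past the line at every such probe set. These were RPS6KA2, a ribosomal S6 kinase with a log2 ratio of 1.29, GRAMD1A, a sterol transfer protein at -1.28, and RGS16, a regulator of G protein signalling that went from 116 to 51.7, the latter below the filter floor of 57.4.

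The lowest log2 ratios by the naming rule belonged to EVPLL (-4.02), the transcription factor STAT5A (-3.84), the water channel AQP5 (-3.29), the transcription factor BATF3 (-3.23), the prostaglandin receptor PTGDR2 (from 177 to 22.2) and SMOC1 (-2.62). They were followed by NEURL1 (-2.45), the flagellin receptor TLR5 (-2.45), PDZD4 (-2.36), GPSM1 (-2.32), NFKBIL1 (-2.29) and the antisense transcript MYRF-AS1 (-2.25). The highest belonged to MUC6, a gel-forming mucin (3.59, from 22.3 to 268), ELK2AP (3.14), the transcription factor OSR1 (2.33), GPR20 (2.25), NEMP2 (2.23) and ROM1 (2.07). Next came CLIP3 (2.02), BRICD5 (1.99), C4BPA, a chain of the complement inhibitor C4b-binding protein (1.98, from 88.2 to 349), WFDC12 (1.98), SPATA32 (1.94) and VCX2 (1.79). Each of these 24 genes rested on 1 probe set above the filter, and none was among the brighter genes. In 11 of the 12 lowest and 10 of the 12 highest, 1 array was below the filter floor of 57.4, so the exact ratios and their order rest on signals that may not differ from background. With such signals raised to that floor, the lowest genes were 2.60-fold to 9.76-fold lower, with AQP5 the furthest, and the highest were 1.96-fold to 4.67-fold higher. For SMOC1, GPSM1, MYRF-AS1, GPR20 and SPATA32 a second, dimmer probe set had a ratio of the opposite sign.

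The stricter filter fixed as an alternative named genes with more signal. The highest of these included F3, the tissue factor that starts blood coagulation, which went from 341 to 1153 (log2 ratio 1.76). The deubiquitinase gene YOD1 had a ratio of 1.33, and CAV2, which encodes a caveolin, had 1.32, from 1171 to 2918. All 3 CAV2 probe sets were higher, by 0.75 to 1.76. C4BPB, the other chain of C4b-binding protein, was at 1.17, from 815 to 1833. Others near a doubling of signal were NUDT16L1 (1.17), CLIC5 (1.09), the acyltransferase gene GPAT3 (1.09), the polarity gene PARD6B (1.06), the glycolytic regulator PFKFB3 (1.06) and the neutrophil chemokine gene CXCL8 (1.06, from 746 to 1551). CACNG4 reached 2.38 and COCH 1.07, but other probe sets of CACNG4 went as low as -0.61 and another of COCH was at 0.01.

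On the lower side of the same filter, below IFITM3 and IFITM2, were CEMIP, a hyaluronan-binding protein gene (-1.13), the retinoic acid receptor gene RARG (-1.07), FBXL15 (-1.03) and FOXA2, a transcription factor of the endoderm (-1.01, with 3 probe sets from -1.23 to -0.58). ZNF574 (-0.98), C1RL (-0.98), the transporter gene SLC16A4 (-0.96), the secreted glutathione peroxidase gene GPX3 (-0.94) and TXNIP, a thioredoxin-binding protein gene (-0.91), followed. TXNIP had 3 probe sets that ranged from -0.98 to -0.85. MUC5AC was at -1.16, but its 4 probe sets ran up to 0.25, and its ratio was 0.25 when probe sets with shared probes were left out.

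**Figure D2:**
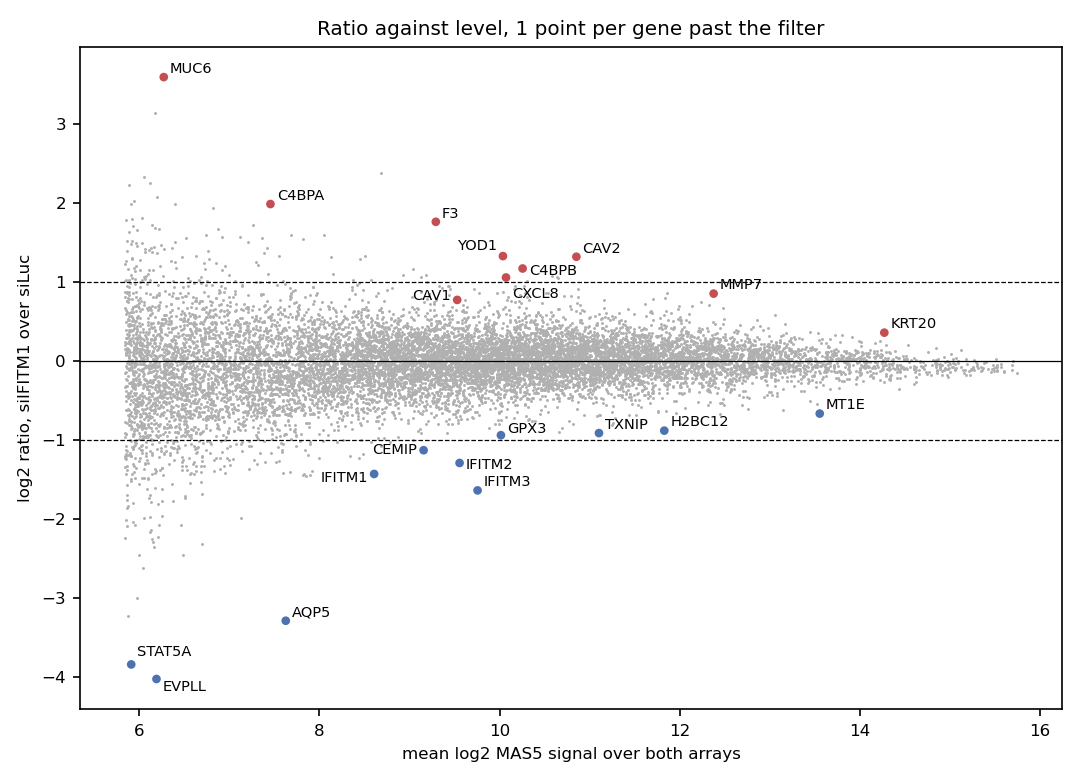
Log2 ratio of siIFITM1 over siLuc (vertical axis) against the mean log2 MAS5 signal of both arrays (horizontal axis), with 1 point per gene past the filter and dashed lines at 2-fold. The scatter narrows with signal, and IFITM1, IFITM2, IFITM3, F3 and CAV2 lie outside it at levels where few genes pass the 2-fold line.

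Of 25 gene lists fixed before the data were examined, 9 had a median log2 ratio outside the central 95% of 10000 random lists matched on signal. For lists of genes that vary independently, 1.25 would be outside. Members of a list may vary together, which random lists do not copy, so 9 against 1.25 does not measure an excess. These percentiles describe the 2 arrays and are not a test. Apart from the IFITM relatives, the list medians lay between -0.24 and 0.14. Some lists outside the random range had a 95% bootstrap interval of the median over members that held 0. These were S phase (-0.02 to 0.18), inflammatory (-0.13 to 0.26), cholesterol (-0.07 to 0.24) and mucus genes (-0.51 to 0.07). The intervals came from 2000 resamples of the members. They treat members as independent and cover no variation between samples, so an interval that leaves out 0 does not set a list apart from 0.

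Genes of cell division were slightly higher with siIFITM1. Among 40 mitosis genes 33 had a ratio above 0, with a median of 0.12, higher than 99.9% of random lists. Examples were NDC80, a kinetochore protein gene (0.36), the cyclin gene CCNA2 (0.36), the kinesin genes KIF4A (0.35) and CENPE (0.34). None of the mitosis genes was 2-fold apart. Among 37 genes of S phase and DNA replication 24 were above 0, with a median of 0.11 (percentile 99.3). The named members went both ways, with POLE2 at 0.38, RFC3 at 0.36, CDC45 at -0.46 and GINS4 at -0.33. Without probe sets that carry shared probes, neither median stayed outside the random range, at 0.089 for mitosis and 0.062 for S phase.

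Histone genes were lower, with 9 of 11 below 0 and a median of -0.23 (percentile 0.13). They included the linker histone gene H1-2 (-1.02) and the core histone genes H2BC5 (-0.91), H2BC12 (-0.88, from 4936 to 2678) and H2AC6 (-0.31). H2BC5 and H2AC6 were read by probe sets that share probes between transcripts. Without such probe sets the histone median was -0.30, still outside the random range. Ribosomal protein genes were lower by a small margin, with 45 of 50 below 0 and a median of -0.10, but the median was -0.00739 after quantile normalization. Examples were RPLP2 (-0.49), RPL27A (-0.44), RPL12 (-0.20) and RPL3 (-0.18). Oxidative phosphorylation genes had a median of -0.05 (32 of 46 below 0), inside the random range, with NDUFB10 at -0.40, NDUFS1 at 0.24, COX5B at -0.23 and COX8A at -0.22.

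Genes of the unfolded protein and amino acid stress response were lower in 30 of 41 cases, with a median of -0.14, below all 10000 random lists. NUPR1, a stress-induced nuclear protein gene, went from 492 to 213 (-1.21), and DDIT4, an inhibitor of mTOR signalling, from 11229 to 7288 (-0.62). VLDLR (-0.52) and the serine synthesis gene PHGDH (-0.48) were also lower. In the heat shock and oxidative stress list the median was 0.00, with 17 of 33 above 0, and 0.15 and outside the random range without shared probes. It held HMOX1, the heme oxygenase gene, at 1.29 (from 223 to 546) and the metallothionein genes MT1E (-0.67, from 15152 to 9546), MT1H (-0.56) and MT1X (-0.44), all 3 read by probe sets that share probes between transcripts. Hypoxia and glycolysis genes had a median of -0.02 (0.018 after quantile normalization) and 17 of 32 below 0, with ALDOC at -0.69, DDIT4 at -0.62 and MXI1 at -0.58 opposite PFKFB3.

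Inflammatory genes had a median of 0.14 (percentile 99.0), although 12 of 28 were below 0 and the median came inside the random range with no filter (0.0897). The chemokine genes CXCL8 (1.06), CXCL1 (from 414 to 826) and CCL20 (0.67) were higher, and CFB, complement factor B, was lower (-0.90). Interferon-stimulated genes other than the IFITM family showed no common direction. Their median was -0.03, with 19 above 0 and 25 below. MX1 (-1.39, from 185 to 70.6) and RSAD2 (-1.01) were lower and SAMD9L was higher (0.52), while TRIM22 went from 75.7 to 52.1, below the filter floor. Of the 17 genes of MHC class I and antigen presentation, 12 were below 0 and the median of -0.09 lay inside the random range. The immunoproteasome genes PSMB8 and PSMB9 were at -0.76 and 0.27, with TAP2 at 0.74 and HLA-G at -0.18. Both immunoproteasome genes were dimmer genes. The 0.27 of PSMB9 was within the SD of 0.496 between dimmer probe sets of the same gene.

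Cholesterol biosynthesis genes had a median of 0.12 (percentile 99.2, 17 of 28 above 0). HMGCS1, an early enzyme of the pathway, went from 2543 to 4373 (0.78), MVK was at 0.49, TM7SF2 at -0.74 and STARD4 at -0.42. Averaging the probe sets of each gene gave a median of 0.063, inside the random range.

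Differentiation genes of the intestinal lining were mixed. Mucus and secretory genes had a median of -0.20 (percentile 1.4, 12 of 18 below 0), with MUC2, the main intestinal mucin gene, at -0.86, the secretory transcription factor gene SPDEF at -0.76 and the trefoil factor gene TFF3 at -0.63. MUC6 was higher, from a siLuc signal below the filter floor. The median lay inside the random range after quantile normalization (-0.15). Absorptive genes had no settled direction. Their median was -0.16, inside the random range, but 0.15 with no filter, with the stricter filter and without shared probes. The members named by the rule were dimmer genes that were lower, GUCA2A (from 88.7 to 44.2, below the filter floor), CA1 (-0.83), CDHR5 (-0.75) and SLC5A1 (-0.65), while 5 of the 7 brighter members were above 0. Targets of Wnt and beta-catenin had a median of -0.11, just inside the random range (percentile 3.29). It was outside after quantile normalization (-0.12) and among the 20 brighter members (-0.17, 14 below 0). The named members were ASCL2, an intestinal stem cell transcription factor gene, at -0.62, BMP4 at -0.54, MMP7 at 0.85 and FOSL1 at 0.52.

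Epithelial adhesion and junction genes had a median of 0.08, inside the random range (percentile 96.3), with 21 of 31 above 0, and 0.15 and outside it without shared probes. DSC2 (0.39), TJP1 (0.38), JUP (0.36) and KRT20 (0.36, from 17466 to 22374) were among the higher members. The 13 measured mesenchymal genes, of which 4 were among the brighter genes, had a median of -0.14, inside the random range. It was -0.39 and outside with no filter, and 0.048 without shared probes. ACTA2 (from 87.5 to 46.4), LOXL2 (from 107 to 57.3) and VIM (from 97.7 to 54.4) had siIFITM1 signals below the filter floor, and TGFB2 was at 0.81. For matrix proteolysis the median was -0.02 (0.0059 after quantile normalization), and 12 of 22 were below 0, among them MMP14 (-0.55). The members named by the rule, MMP7 (0.85, from 3958 to 7141), the protease inhibitor gene TIMP2 (0.79), the urokinase gene PLAU (0.76) and MMP11 (0.92), were higher. Integrin, focal adhesion and caveolar genes were split evenly, with 15 of 30 above 0, and the 4 members named by the rule were all higher. These were CAV2 (1.32), the matricellular gene CCN1 (0.87), the collagen receptor gene ITGA2 (0.86) and CAV1 (0.77, from 565 to 965).

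The remaining lists lay inside the random range. p53 targets had a median of 0.08 (-0.05 among brighter genes) and 13 of 24 above 0, with TP53INP1 at 1.17 (from 56.3, below the filter floor, to 127), PLK3 at 0.81, TIGAR at -0.46 and GDF15 at -0.45. Immediate-early and MAPK feedback genes had a median of 0.02 with 14 of 32 below 0. The members named by the rule were higher, with DUSP5 at 0.92, FOSB at 0.55, EPHA2 at 0.55 and FOSL1 at 0.52. For the RNA interference machinery the median was 0.08 with 8 of 14 above 0. Examples were AGO2 at 0.28, XPO5 at 0.27, AGO1 at 0.12 and DROSHA at -0.11. Of the measured markers of other cell types, 1 leukocyte gene, LYN, was among the brighter genes. The 9 measured genes of the leukocyte list, which also holds the hemoglobin gene HBB, had a median of -0.13. CORO1A was at -0.87, CD79A at -0.79, CD14 at -0.33 and HBB at 0.59. The 7 genes of fibroblasts and endothelium had a median of -0.24, with LUM at 1.54 (from 132 to 386) and CLDN5 going from 84.3 to 47.4, below the filter floor.

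**Figure D3:**
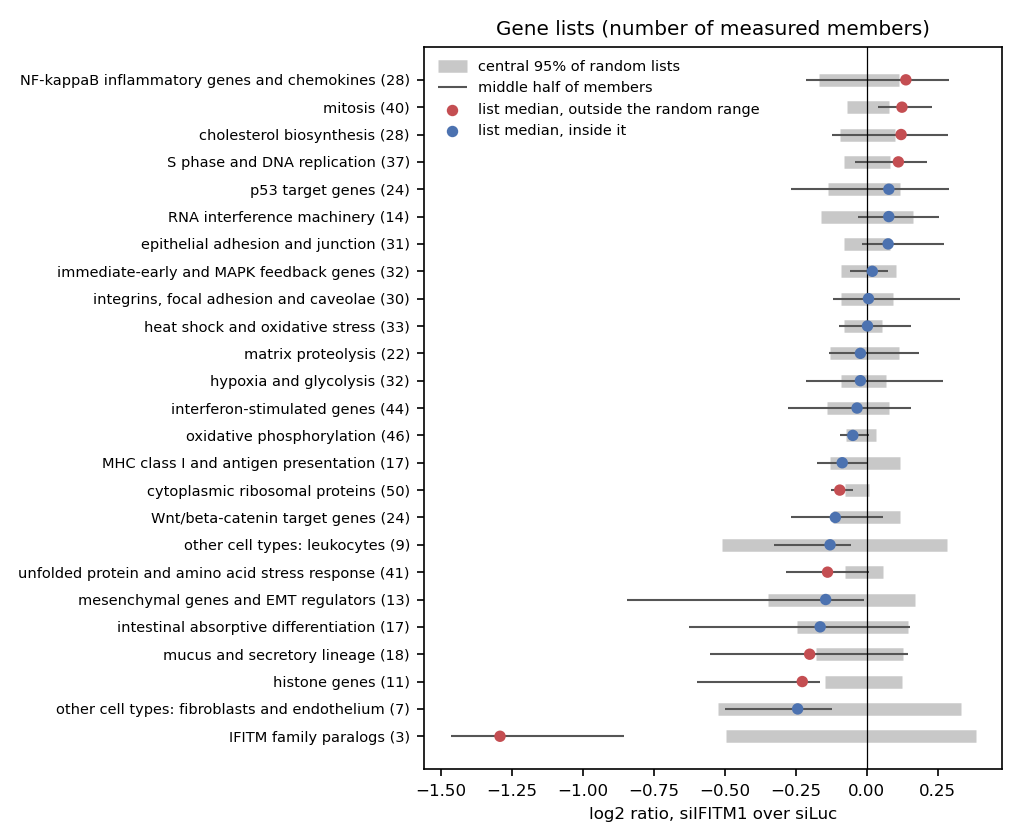
Median log2 ratio (points) of each of the 25 gene lists, with the number of measured members in brackets, the central 95% of 10000 random lists of matched signal (grey bars) and the interquartile range of the members (thin lines). The 9 medians outside the random range are drawn in red, and the IFITM relatives lie furthest from 0.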

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

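The tests of the 3 patterns weighed here were chosen after the results were seen.

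Among 3186 probe sets above the filter that name no gene in the probe table, and that entered no comparison, 85 were at least 2-fold above the siLuc array and 108 were at least 2-fold below it. Among the 777 of these above the 75th percentile of signal, 4 were 2-fold higher and 0 were 2-fold lower. No explanation was tested for them.

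IFITM2 and IFITM3 were lower together with IFITM1. Of the 500 genes nearest in signal to IFITM2, 0% had a ratio as low as its -1.29 (upper limit 0.735%). This argues against the ordinary spread between genes of similar signal on the 2 arrays. The limit treats genes as independent and does not cover variation between cultures. With 1 sample per siRNA, a difference between the samples unrelated to the siRNA is not excluded. A loss of interferon-stimulated transcripts in general was weighed by the median of the other members, which was -0.034 (bootstrap interval -0.16 to 0.07). Among the 24 brighter members it was -0.098, with 14 below 0. These values argue against a general loss about as large as that of the IFITM genes. A smaller loss, or a loss in some members only, is not excluded. Cross-hybridisation of IFITM1 transcripts to the probes of its relatives, and a loss of IFITM2 and IFITM3 mRNA through the siRNA, cannot be told apart, because 0 probe sets of IFITM1, IFITM2 or IFITM3 lack shared probes. The sequences of the siRNA and of the probes, which could separate these, were not used here.

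More genes were 2-fold lower than higher. After subtraction of the loess trend of ratio on signal, 58% of the genes past the 2-fold line were still lower (exact interval 52.6% to 63.2%). Removing the trend thus reduced the 66.5% but left lower genes in the majority. The interval covers counting error only and treats genes as independent, so it cannot settle whether the trend accounts for all of the imbalance. Among brighter genes the lower share was 33.3% (14.6% to 57.0%, from 21 genes), against 68.5% among dimmer genes (63.3% to 73.3%). The imbalance was thus found among dim probe sets, where the siIFITM1 signals were lower by a median log2 ratio of -0.09. A difference in background between the arrays and a biological loss of weakly expressed transcripts both remain open, and neither was tested.

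Mitosis genes were higher with siIFITM1. Their median lay at percentile 99.8 of random lists after quantile normalization and 99.9 after loess. These percentiles could hardly test a trend with signal, because the random lists were already matched on signal. The median itself was 0.11 after quantile normalization and 0.12 after loess, so removing such a trend left it nearly unchanged. Without probe sets that carry shared probes 30 genes remained, 21 of them above 0, and the median lay at percentile 94.2, so such probe sets may contribute, and the smaller list leaves this undecided. The labels give 1 sample per siRNA, so an effect of IFITM1 depletion cannot be told apart from a difference in growth between the samples.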

How the results depend on the processing

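All alternatives here were fixed before the data were examined except the ranking against the running spread and the raising of low signals to the filter floor. No paired analysis was possible because each siRNA had 1 array and no test was made. The log2 ratio of IFITM1 stayed between -1.43 and -1.32. It had no value under the stricter filter, whose floor lies just above its signal, or without probe sets that carry shared probes. Of 1184 recomputed ratios of 140 named genes, 1136 stayed within the spread at their signal level, 47 moved beyond it with the same sign and 1 reversed, MUC5AC, at 0.25 without shared probes. Part of the count that stayed was fixed in advance. A change of filter keeps the same probe set for a gene, and averaging changes nothing where 1 probe set passed. Of 196 recomputed list medians, 16 changed sign, in 9 lists that were all inside the random range as reported. They included absorptive genes, at 0.15 with no filter, with the stricter filter and without shared probes, p53 targets, at -0.05 with the stricter filter, and hypoxia genes, at 0.12 without shared probes.

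The 2-fold counts moved with the filter, the threshold and the demand on probe sets. Higher and lower genes numbered 62 and 99 with a pseudocount of 32, 1778 and 2172 with no filter, 14 and 7 with the stricter filter, 511 and 897 at 1.5-fold, 27 and 44 at 3-fold, and 1 and 2 where at least 2 probe sets had to pass. The lower share was 63.9% after median centring, 58.0% after quantile normalization and 55.0% with no filter. Low signal over background limits the dimmer genes.

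Without shared probes, the medians for mitosis (0.089), S phase (0.062), cholesterol (0.066) and mucus genes (-0.13) came inside the random range, those for epithelial (0.15) and heat shock genes (0.15) went outside it, and those for mesenchymal (0.048) and oxidative phosphorylation genes (-0.00843) moved. Quantile normalization brought ribosomal (-0.00739) and mucus genes (-0.15) inside, took Wnt targets (-0.12) outside and moved oxidative phosphorylation genes (-0.00995). Loess brought mucus genes inside (-0.15) and moved ribosomal genes (-0.057). With the mean over probe sets, cholesterol (0.063) and mucus genes (-0.16) came inside and epithelial genes (0.097) went outside. No filter brought inflammatory genes inside (0.0897) and took epithelial (0.075) and mesenchymal genes (-0.39) outside. The pseudocount brought mucus genes inside (-0.17), and the stricter filter took Wnt targets outside (-0.17). The cause of these shifts was not tested.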

Other observations

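The ranking against the running spread at each signal level was chosen after the data were seen, and the tests of let-7 targets and of neighbouring genes were written down before their results were seen.

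Ranked against the spread of genes of similar signal, several abundant transcripts stood beside the IFITM genes. MT1E (-0.67), H2BC12 (-0.88), TXNIP (-0.91) and LGALS1, which encodes galectin-1 (-0.81, from 3213 to 1838), were among the 12 lowest. MT1E went from 15152 to 9546, at a level where ratios were narrowly spread. MT1F (-0.42) was lower like MT1H and MT1X, but all 4 were read by probe sets that share probes between transcripts, so they do not count as separate measurements. Among the 12 highest were PANX1, a membrane channel gene whose brightest probe set went from 1116 to 2310 (1.05) and whose 4 probe sets ranged from 0.091 to 1.07, and SRFBP1 (1.33, from 229 to 576).

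HMGA2 (0.86), YOD1 (1.33) and DICER1 (0.49) are known targets of the let-7 microRNA family, and a candidate explanation for their higher ratios is release of let-7 targets. Both samples received an siRNA, so competition for the silencing machinery would act on both and does not by itself predict a difference. The 6 probe sets of HMGA2 past the filter ran from -0.48 to 0.86 and those of DICER1 from -0.47 to 0.66, so both directions occurred. Of 25 other let-7 targets listed beforehand, 14 were measured. Their median was 0.12, with 10 above 0, at percentile 93.5 of random lists, which leaves the hypothesis undecided. CDC25A (0.63) and TGFBR1 (0.41) were the highest of them and NR6A1 the lowest, from 83.4 to 47.7, below the filter floor.

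CAV1 with CAV2, and C4BPA with C4BPB, are neighbours in the genome and were higher together. Over 6925 pairs of neighbouring protein-coding genes with different name stems, Spearman's rho of the log2 ratios across genes was 0.0499, above the range of -0.02 to 0.03 from 1000 random pairings. Genes are not independent replicates, and a rho of this size may reflect shared regulation or shared technical properties of nearby genes. Over the 349 neighbouring pairs with the same name stem, to which these genes belong, rho was 0.09, at percentile 96 of random pairings and inside their range of -0.10 to 0.10. This rho thus includes the pairs that prompted the test. It also includes IFITM1 with IFITM2 and IFITM1 with IFITM3, which are neighbours read by probe sets that share probes between transcripts. With so few pairs a correlation of this size could not be told from chance, so the test decides nothing for related neighbours.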
